A study of Streptomyces coelicolor A3(2) with 24 samples.

How the data were processed

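RNA was sequenced from 24 samples of the M145 strain of Streptomyces coelicolor and of a strain without rokL6, in 8 groups of strain, medium and time with 3 libraries each. Per the labels' protocols, RNA was isolated with a modified Kirby mix and column purification, and libraries were made with a non-directional kit after a step on poly-T beads, which is unusual for bacterial RNA. The labels do not say how ribosomal RNA was removed. Genes annotated as ribosomal RNA held 0.311 to 1.25% of the counts, small RNA genes 3.42 to 8.31%, and SCOs02 alone 2.92 to 7.10%. The culture source of each replicate, the read length and the sequencing batches are not given in the sources used here.

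The deposited files hold raw fragment counts per gene, 1 file per library. Per the submitters' processing notes, Trimmomatic 0.36, Bowtie2 2.4.3 and SAMtools 1.11 were used, with no roles stated. Per the file headers, the authors counted fragments per gene with featureCounts 2.0.1 from paired reads, with no strand option and no option for fragments that overlap several genes, on the ASM20383v1 assembly. Without a strand option, a fragment that lies in a gene is counted there whichever strand it came from. Each file lists 8239 genes, 7854 on the chromosome and 385 on plasmids, and the plasmid genes had 0 counts in each library. Of these genes, 7932 matched the reference table of the same assembly by locus tag, which gave symbols and coordinates. Where 1 symbol stood for more than 1 gene the locus tag is given. Symbols missing from the table were taken from gene lists written before the data were examined.

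Totals ran from 7779982 to 11249480 fragments per library. Levels are CPM, counts scaled to the TMM-adjusted library total, except in the genes silent elsewhere, where the unscaled total was used. With a floor of 3 counts per library, a gene at 0 counts lies below about 0.292 to 0.364 CPM as a group mean. Replicates were checked for copies of one another: over the 24 pairs of replicates within groups, chi-square per degree of freedom was 3.85 to 360, so no pair repeated the same library.

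Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by filterByExpr over the 8 groups, which left 7712 of 8239, and libraries were scaled by TMM. The 24 libraries were fitted in 1 edgeR quasi-likelihood model with a mean per group. There were 14 comparisons: the strains in each medium and time (4), GlcN against mannitol in each strain and time (4), 48 h against 24 h in each strain and medium (4), and the difference between the strains' GlcN effects at each time (2). The quasi-likelihood F test was used with Benjamini-Hochberg adjustment over the genes tested, and genes with adjusted p under 0.05 passed. These choices, the gene lists and the rule for naming genes were made before the data were examined.

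The 37 gene lists held 434 members in antibiotic and other gene clusters, developmental genes, stress and transport genes and metabolic pathways, from general knowledge of the species. They were tested with camera at a preset correlation of 0.01, with adjustment over the 37 lists of a comparison, then with camera at an estimated correlation and with fry. SCO1447 was left out of the list tests. Counts of members past the test are given over all genes tested and adjusted over the list alone. Overlaps between comparisons are given with the number expected by chance (the product of both counts over the genes tested). Neighbouring genes can move together, so large overlaps can arise by chance more often than for independent genes.

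Genes were named by a fixed rule. SCO1447 and SCO1448 were named in each strain comparison. So were, among genes that passed, did not overlap in CPM between the groups and reached a mean of 10 CPM in a group, the 8 with the largest rises and the 8 with the largest falls (5 and 5 for time). The rule also took up to 4 members with the smallest p in lists that passed or held members past the test, and the 8 smallest p of each interaction, and the text gives a selection. For 3 against 3 libraries, chance leaves 10% of genes without overlap. The genes gdhA, sapA and SCO3356 to SCO3359 were named because they were the few members moving against their lists, chosen after their values were seen.

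Whether the replicate numbers pair the libraries was checked in 12 comparisons by correlating, across genes, the deviations from the group means of libraries with the same number. The lowest of these correlations was −0.841 and the highest 0.679. In mannitol at 24 h the 3 values of the strain comparison were all above 0.1 (0.156, 0.428 and 0.359), so the numbers may pair there. The labels state no pairing, and 1 of 12 comparisons may pass such a bound by chance. In the other 11 comparisons at least 1 was lower.

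The alternatives tried were RLE size factors in place of TMM, no filter except on genes at 0 counts throughout, DESeq2, a fit of only the groups compared, the replicate number as a block, the 10 most abundant genes left out, and each replicate left out in turn. A fit without both atypical mannitol 48 h libraries was added after the data were seen. The procedure was tested on simulated data with known changes over the 14 comparisons. It recovered 19 to 56% of genes changed 2-fold and 68 to 86% of genes changed 4-fold, with at most 9.49% false calls. A list with a built-in change was called in 14 of 14 comparisons and 0 of 504 tests of other lists were called. Genes were drawn independently of one another there. The simulation therefore cannot show how often lists of correlated genes are called falsely. No simulated library stood apart from its group as the atypical libraries did. The share of false calls in comparisons that hold those libraries was therefore not tested.

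Left out were the 527 genes with too few counts and any measure that needs reads or a genome sequence, such as coverage along a gene or strand. Read data were not used here.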

Results

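RNA was sequenced from Streptomyces coelicolor M145 (WT) and from a null mutant of rokL6 (SCO1447), a gene for a regulator of the ROK family. Both strains grew on minimal medium agar with mannitol or with mannitol and glucosamine (GlcN), an amino sugar. The labels give 24 h with the description VEG and 48 h with the description SPO. The deposited file names give other hours, 24 and 42 for mannitol and 26 and 44 for GlcN, so the media were not sampled at equal ages if those hours are right. The 8 groups of strain, medium and time held 3 libraries each. Between 7779982 and 11249480 fragments per library were assigned to genes. Of 8239 genes, 7712 had enough counts to be tested, and the 385 plasmid genes had 0 counts in the 24 libraries. Levels are given as CPM (counts scaled to the library total; mean ± SD, n = 3), and changes as log2 fold changes (± SE). No source used here says that the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between samples. Fold limits for genes at 0 counts cover counting error only.

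WT mannitol 48 h replicate 1 and rokL6 mannitol 48 h replicate 3 stood apart from the other 22 libraries. In the 500 genes of at least 300 bp with the lowest counts elsewhere, the median was 26.5 and 58.8 CPM per kb in this pair, against 1.16 to 1.71 in the other 22 libraries. The lowest correlation across genes with another library of the same group was 0.888 and 0.764 for these 2 libraries, against 0.9855 or more in the 6 groups without them. Genes are not independent replicates, so these correlations describe likeness only. All 24 libraries were kept in the tests. The pair raised the spread of every test, which shares 1 spread estimate across groups: the common biological coefficient of variation was 0.335 with them and 0.138 without them. Values without the pair are given beside many of the results they changed. The other WT mannitol 48 h libraries, replicates 2 and 3, also differed from each other. Their chi-square per degree of freedom was 103, against 115 and 125 for replicate 1 set against them.

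**Figure D1:**
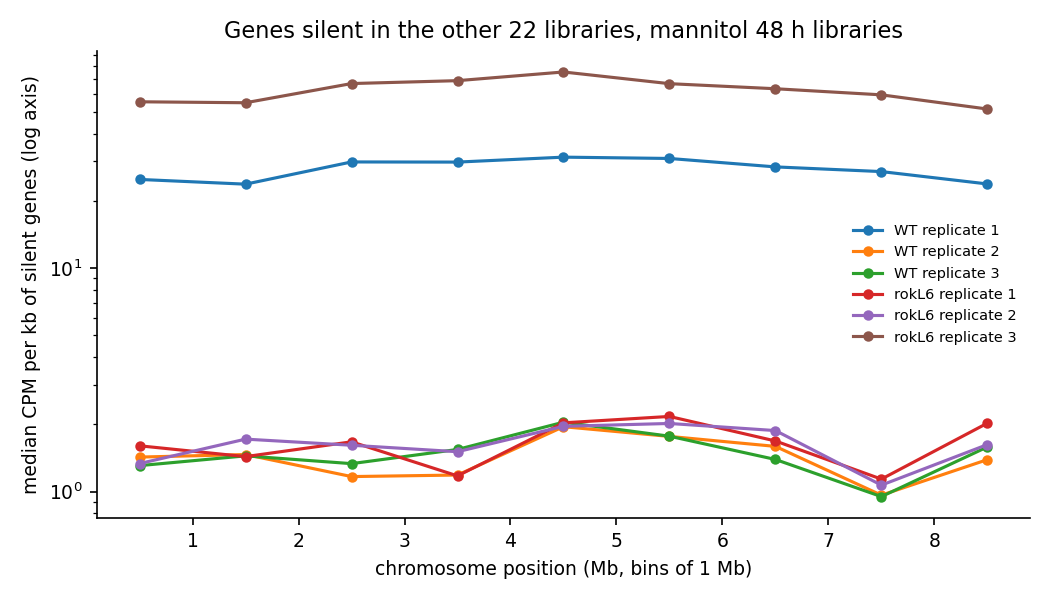
Median CPM per kb (log axis) of the 500 genes with the lowest counts in the other 22 libraries, by position on the chromosome in Mb, 1 line per mannitol 48 h library. WT replicate 1 (26.5 CPM per kb over the 500 genes) and rokL6 replicate 3 (58.8) lie above the other 4 libraries in each bin.

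The first question was what the loss of rokL6 changed, and the deleted gene is given first. SCO1447 had 0 counts in each of the 12 mutant libraries. In WT it had 223 to 464 counts per library, at 30.5 ± 3.05 CPM in mannitol at 24 h, 28.3 ± 0.618 in GlcN at 24 h, 35 ± 8.03 in mannitol at 48 h and 26.5 ± 3.48 in GlcN at 48 h. With a floor of 3 counts per mutant library, its level was at least 83.8-fold, 84.9-fold, 120-fold and 80.2-fold lower in the mutant in these 4 conditions. Both atypical libraries raised the mannitol 48 h limit. WT replicate 1 stood at 44.3 CPM, against 30.3 and 30.5 in replicates 2 and 3. The TMM factor of rokL6 replicate 3 (1.83) lowered the floor. SCO1448, the next gene on the chromosome, is a predicted transporter gene, and the series title names it as the target of RokL6. It rose in rokL6 in the 4 conditions, from 5.13 ± 1 to 1489 ± 29.2 CPM in mannitol at 24 h (8.18 ± 0.62, adjusted p 4.93e-08). In GlcN at 24 h it rose from 66.5 ± 12.3 to 1678 ± 50.5 CPM (4.66 ± 0.52, adjusted p 2.99e-05). At 48 h the change was 6.65 ± 0.57 in mannitol (adjusted p 6.62e-07) and 8.01 ± 0.61 in GlcN (adjusted p 8.05e-08). Without the pair of atypical libraries the mannitol 48 h value was 8.17. With the 6 mannitol 48 h libraries fitted alone, neither SCO1447 (adjusted p 0.317) nor SCO1448 (adjusted p 0.907) passed the test.

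**Figure D2:**
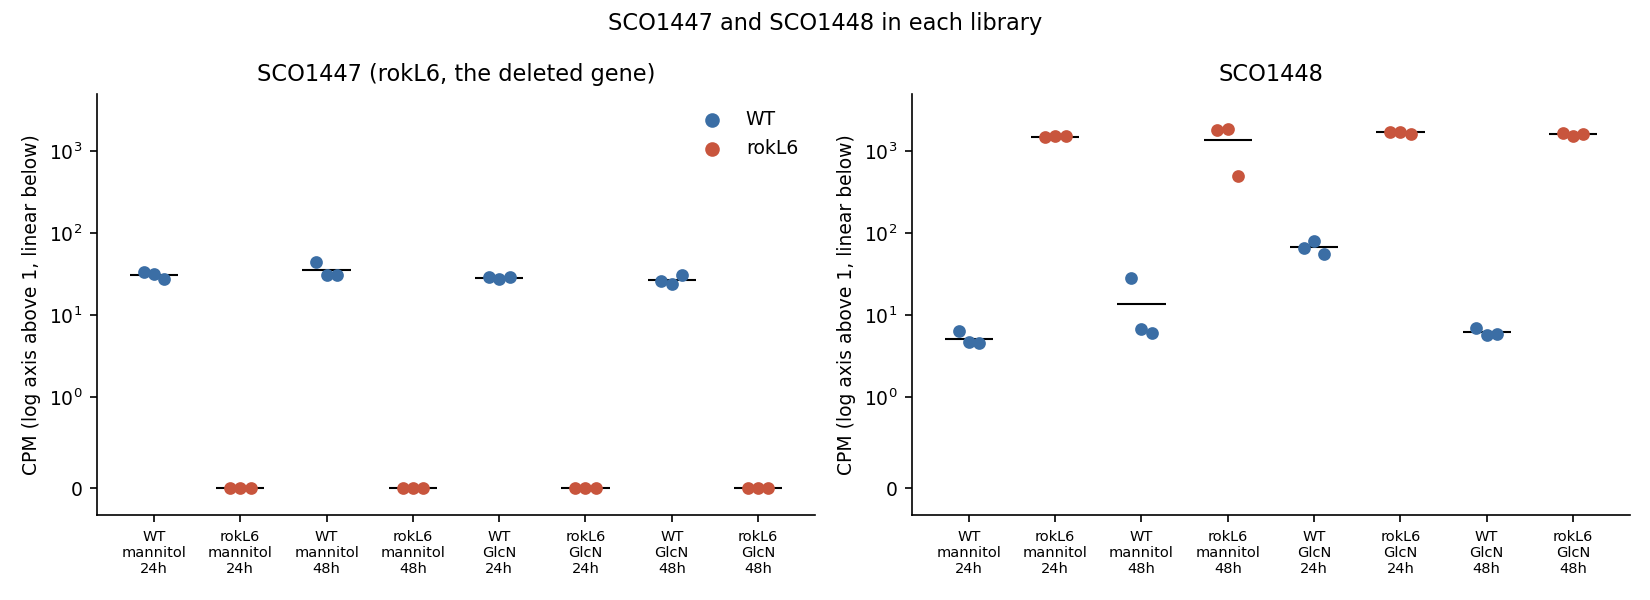
CPM of SCO1447 (left) and SCO1448 (right) in each library by group, WT in blue and rokL6 in red, with the group mean as a line; the axis is logarithmic above 1 and linear below. SCO1447 is at 0 in the 12 mutant libraries, and mean SCO1448 levels run from 1372 to 1678 CPM in the mutant groups against 5.13 to 66.5 CPM in the WT groups.

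The genes beside SCO1447 and SCO1448 also rose in rokL6 in the 4 conditions. SCO1449, which lies on the opposite strand and overlaps SCO1448 by 41 bp, rose by 6.49 and 3.92 at 24 h and by 5.16 and 6.37 at 48 h (mannitol and GlcN). The libraries were not stranded, so its level is uncertain. SCO1446 rose by 2.73, 3.20, 2.59 and 3.09, and SCO1450 by 2.30, 2.44, 2.03 and 2.14. Of the 5 neighbouring genes fixed as a list (SCO1445, SCO1446 and SCO1448 to SCO1450), 4 rose in each condition, and 5 did when adjusted over the list alone. The list passed the camera test in the 4 conditions, also with an estimated correlation (adjusted p 9.18e-10, 6.75e-08, 1.65e-06 and 3.77e-10). SCO1446, SCO1448, SCO1449 and SCO1450 were the 4 genes higher in rokL6 in both media at 24 h (0.00726 shared genes by chance).

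In mannitol at 24 h, 8 genes rose and 3 fell in rokL6 among 7712 tested. SCO0638 rose from 16.8 ± 1.64 to 377 ± 146 CPM (4.49 ± 0.33, adjusted p 4.91e-08). SCO0632 rose by 3.70 and SCO0637 by 1.87, both close to SCO0638 on the chromosome. SCO0555 rose by 3.28 (adjusted p 0.0433). The falls besides SCO1447 were aztA (SCO0476), a zinc transporter gene, at -2.96 ± 0.48 (adjusted p 0.00446), and SCO2519 at -1.95 (adjusted p 0.0268). In this comparison libraries of the same number varied together. With the number as a block, SCO0555 (adjusted p 0.0867) and SCO2519 (adjusted p 0.0700) did not pass and 9 genes did. Leaving out any 1 of the 6 libraries ended the call of SCO0555 (adjusted p 0.0628 to 0.421). That of SCO2519 ended without WT replicates 1 or 2 or rokL6 replicates 1, 2 or 3 (adjusted p 0.0706 to 0.348), and that of aztA without rokL6 replicate 1 (adjusted p 0.0561). Fitted on these 6 libraries alone, SCO0637 (adjusted p 0.0979) and SCO2519 (0.377) did not pass. DESeq2 found 9 genes higher and 8 lower, and without the pair of atypical libraries 14 were higher and 4 lower. Among the 37 lists, camera found 3 higher and 3 lower. The coelimycin antibiotic cluster had a median of 0.67 with 0 of 20 genes past the edgeR test, and 0 adjusted over the list alone (camera adjusted p 4.23e-17, and 0.0421 with an estimated correlation). That estimate gave adjusted p 0.56 without the pair of atypical libraries, and the list did not pass by fry (adjusted p 0.28).

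In GlcN at 24 h, 7 genes rose and 7 fell in rokL6. The falls besides SCO1447 included 4 carotenoid-region genes whose WT levels varied widely. SCO0185 went from 74 ± 85.9 to 1.92 ± 1.02 CPM (-5.29 ± 0.84, adjusted p 0.00479), and crtI (SCO0186, -3.76), SCO0191 (-2.63) and SCO0192 (-2.24) fell too. Without WT replicate 3 the changes of these 4 genes were -3.74, -1.89, -1.46 and -1.59. The lon protease gene (SCO5285) changed by -1.39 and SCO6564 by -0.72. SCO5800 rose by 1.06, and SCO7843 and SCO0005, near opposite ends of the chromosome, by 0.96 and 0.91. Of the 9 genes outside the SCO1447 region, each lost its call when some single library was left out. SCO0185 lost it without rokL6 replicates 1 or 2 (adjusted p 0.0574 to 0.0606) and SCO0191 without rokL6 replicates 1, 2 or 3 (adjusted p 0.0825 to 0.138). The calls of crtI ended without WT replicate 3 or rokL6 replicates 1, 2 or 3 (adjusted p 0.109 to 0.258) and of SCO0192 without WT replicate 3 or rokL6 replicates 1, 2 or 3 (adjusted p 0.0543 to 0.138). For SCO5800 they ended without WT replicates 1 or 2 or rokL6 replicates 1 or 3 (adjusted p 0.105 to 0.196), for SCO7843 without WT replicates 1 or 2 or rokL6 replicates 1 or 3 (adjusted p 0.238 to 0.332) and for SCO0005 without WT replicates 1 or 2 or rokL6 replicates 1 or 3 (adjusted p 0.207 to 0.268). For lon this was so without WT replicates 1 or 2 or rokL6 replicates 1, 2 or 3 (adjusted p 0.0954 to 0.425), and for SCO6564 without WT replicates 2 or 3 or rokL6 replicates 1, 2 or 3 (adjusted p 0.0787 to 0.487). The count was 9, 30, 5, 8 and 6 without WT replicate 2 or 3 or rokL6 replicate 1, 2 or 3. With RLE scaling 9 genes passed, without SCO5800, SCO7843, SCO0005, lon and SCO6564 (adjusted p 0.0997 to 0.199). Fitted on these 6 libraries alone 37 passed, without SCO0185, crtI, SCO0191, SCO0192, SCO7843, SCO0005, lon and SCO6564 (0.0537 to 0.0959), and DESeq2 found 24. With the pair of atypical mannitol libraries left out of the shared spread, 149 genes passed (106 higher, 43 lower), the 14 genes among them.

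Camera found 6 lists higher and 7 lower in rokL6 in GlcN at 24 h. In the carotenoid cluster 3 of 7 genes fell and 4 did not pass, with 6 lower adjusted over the list alone (median -2.63, camera adjusted p 2.41e-17, and 0.0286 with an estimated correlation). The last value was 0.459 without the pair of atypical libraries, and the list did not pass by fry (adjusted p 0.174). The chaplins and rodlins, proteins on the surface of aerial hyphae, had a median of 0.97 with 0 of 10 genes past the test and 4 higher adjusted over the list alone. Their camera call (adjusted p 6.10e-10) was lost with adjusted p = 0.249 with an estimated correlation.

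In mannitol at 48 h, 13 genes rose and 13 fell in rokL6, and this comparison holds both atypical libraries. SCO5265 and SCO5264, adjacent genes, fell from 271 ± 96.9 to 66.4 ± 10.9 CPM (-2.03 ± 0.18, adjusted p 7.86e-07) and from 326 ± 111 to 92.8 ± 6.48 CPM (-1.81 ± 0.17, adjusted p 1.20e-06). Their calls held without any 1 of the 6 libraries. The phosphate-binding protein gene pstS (SCO4142) rose from 23.4 ± 13.9 to 86.8 ± 25.4 CPM (1.89 ± 0.35, adjusted p 0.0172). That call ended without rokL6 replicate 1 (adjusted p 0.0891). SCO3474, SCO3476, SCO3477, SCO3478, SCO3479 and SCO3480, neighbouring genes, rose by 1.00 to 1.44. The quinolinate synthase gene nadA (SCO2162, -1.44), SCO2917 (-1.27) and SCO2492 (-1.02) fell. The call of SCO3476 ended without WT replicate 2 or rokL6 replicate 1 (adjusted p 0.0693 to 0.086), of nadA without WT replicates 2 or 3 or rokL6 replicate 1 (adjusted p 0.0844 to 0.199), of SCO2917 without WT replicate 2 (adjusted p 0.0541) and of SCO2492 without WT replicates 2 or 3 or rokL6 replicate 1 (adjusted p 0.114 to 0.211). The other 5 genes of the SCO3474 group lost theirs without WT replicate 2 or rokL6 replicate 1, and without WT replicate 3 too (adjusted p 0.0583 to 0.148), and SCO3479 also without rokL6 replicate 2 (adjusted p 0.0542).

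The number of genes past the test in mannitol at 48 h moved with single libraries. It was 776, 11 and 14 without WT replicate 1, 2 or 3, and 17, 144 and 280 without rokL6 replicate 1, 2 or 3. Without both atypical libraries it was 396 (180 higher, 216 lower), the 26 genes among them. Fitted on these 6 libraries alone, 0 genes passed by edgeR. In the fit of all libraries 603 genes had an unadjusted p under 0.05, and DESeq2 found 84. RLE scaling gave 11 genes, 7 higher and 4 lower, without SCO3474, SCO3477 to SCO3480, nadA and SCO2492 among others. Of the 37 lists camera found 6 higher and 13 lower, 2 of which held with an estimated correlation, and 7 higher and 4 lower without the atypical pair. In the phosphate starvation list 1 of 9 genes rose and 5 did adjusted over the list alone (median 0.48, camera adjusted p 6.02e-08, and 0.0256 with an estimated correlation). In the cluster for coelichelin, an iron-binding compound, 0 of 11 genes passed and 9 were lower adjusted over the list alone (median -0.56, camera adjusted p 6.68e-13). This was adjusted p = 0.152 with an estimated correlation.

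In GlcN at 48 h, 23 genes rose and 2 fell in rokL6. SCO3474 and SCO3476 to SCO3480 rose again, by 1.17 to 1.85. SCO3477 went from 27.2 ± 6.95 to 97.8 ± 42.8 CPM (1.85 ± 0.27, adjusted p 0.00119). The molybdate transporter gene modA (SCO3704) rose by 2.24, SCO3705 by 2.47, SCO6429 by 1.99 and SCO6433 by 1.96, with SDs in the mutant near the size of the means. Without rokL6 replicate 2 these changes were 1.17, 1.49, 1.44 and 1.37. SCO2492 fell from 92.6 ± 6.85 to 30.3 ± 4.57 CPM (-1.61 ± 0.21, adjusted p 3.89e-04), and SCO1447 was the other fall. The call of modA ended without WT replicates 1 or 3 (adjusted p 0.0708 to 0.0884), of SCO3705 without WT replicates 1, 2 or 3 or rokL6 replicate 2 (adjusted p 0.124 to 0.693), of SCO6429 without WT replicates 1 or 3 or rokL6 replicate 2 (adjusted p 0.145 to 0.164) and of SCO6433 without WT replicates 1 or 3 or rokL6 replicate 2 (adjusted p 0.227 to 0.289). Fitted on these 6 libraries alone, modA, SCO3705, SCO6429 and SCO6433 did not pass (adjusted p 0.0523 to 0.114) and 95 genes did. DESeq2 found 32 higher and 13 lower. SCO3479 and SCO3480 lost their calls without WT replicates 1 or 3 or rokL6 replicate 2 (adjusted p 0.0740 to 0.151). The count was 10, 10 and 11 without WT replicate 1, WT replicate 3 or rokL6 replicate 2, and 75 without the atypical mannitol libraries (42 higher, 33 lower), the 25 genes among them. At 48 h both media shared 10 higher genes (0.0388 by chance), the 4 neighbours of SCO1447 and the 6 genes of the SCO3474 group. They shared 2 lower genes, SCO1447 and SCO2492. The shared higher genes are groups of neighbours that can move together, so they are not 10 independent agreements.

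Camera found 1 list higher and 2 lower in rokL6 in GlcN at 48 h. In the actinorhodin antibiotic cluster 0 of 22 genes passed the edgeR test and 8 were lower adjusted over the list alone (median -1.16, camera adjusted p 6.13e-37, and 0.0132 with an estimated correlation). This list did not pass by fry (adjusted p 0.219). Arginine biosynthesis had 0 of 7 genes past either test (median -0.24, camera adjusted p 2.41e-05), with adjusted p = 0.425 with an estimated correlation. Over the comparisons with 0 list members past the test, 125 to 603 genes of all tested had an unadjusted p under 0.05 by edgeR, and DESeq2 found 17 to 84 genes.

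The effect of GlcN was asked in each strain at each time. At 24 h, 1516 genes rose and 1095 fell with GlcN in WT, and 1445 rose and 943 fell in rokL6. Of these, 1245 rose in both strains (284 by chance) and 816 fell in both (134 by chance), and the log2 fold changes of the strains correlated across genes (r = 0.937). SCO5086 of the actinorhodin cluster rose from 2.48 ± 0.915 to 1195 ± 234 CPM in WT (8.92 ± 1.06, adjusted p 1.41e-06) and by 8.48 in rokL6. SCO5888 of the undecylprodigiosin cluster rose by 8.16 and 8.45. The rodlin gene rdlA (SCO2718) fell from 2167 ± 2110 to 5.56 ± 2.92 CPM in WT (-8.61 ± 0.97, adjusted p 7.31e-07) and also in rokL6 (-7.81). The chaplin gene chpD (SCO2717) fell too (-7.43 and -6.58). Without WT mannitol replicate 3 the WT changes were -7.46 for rdlA and -6.32 for chpD. SCO1448 rose with GlcN in WT (3.69 ± 0.51, adjusted p 9.23e-06) and did not pass in rokL6 (0.17, adjusted p 0.829). Without the atypical mannitol 48 h libraries 4493 genes passed in WT and 4265 in rokL6, and with only the 6 libraries of each comparison fitted 4473 and 4446 did.

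**Figure D3:**
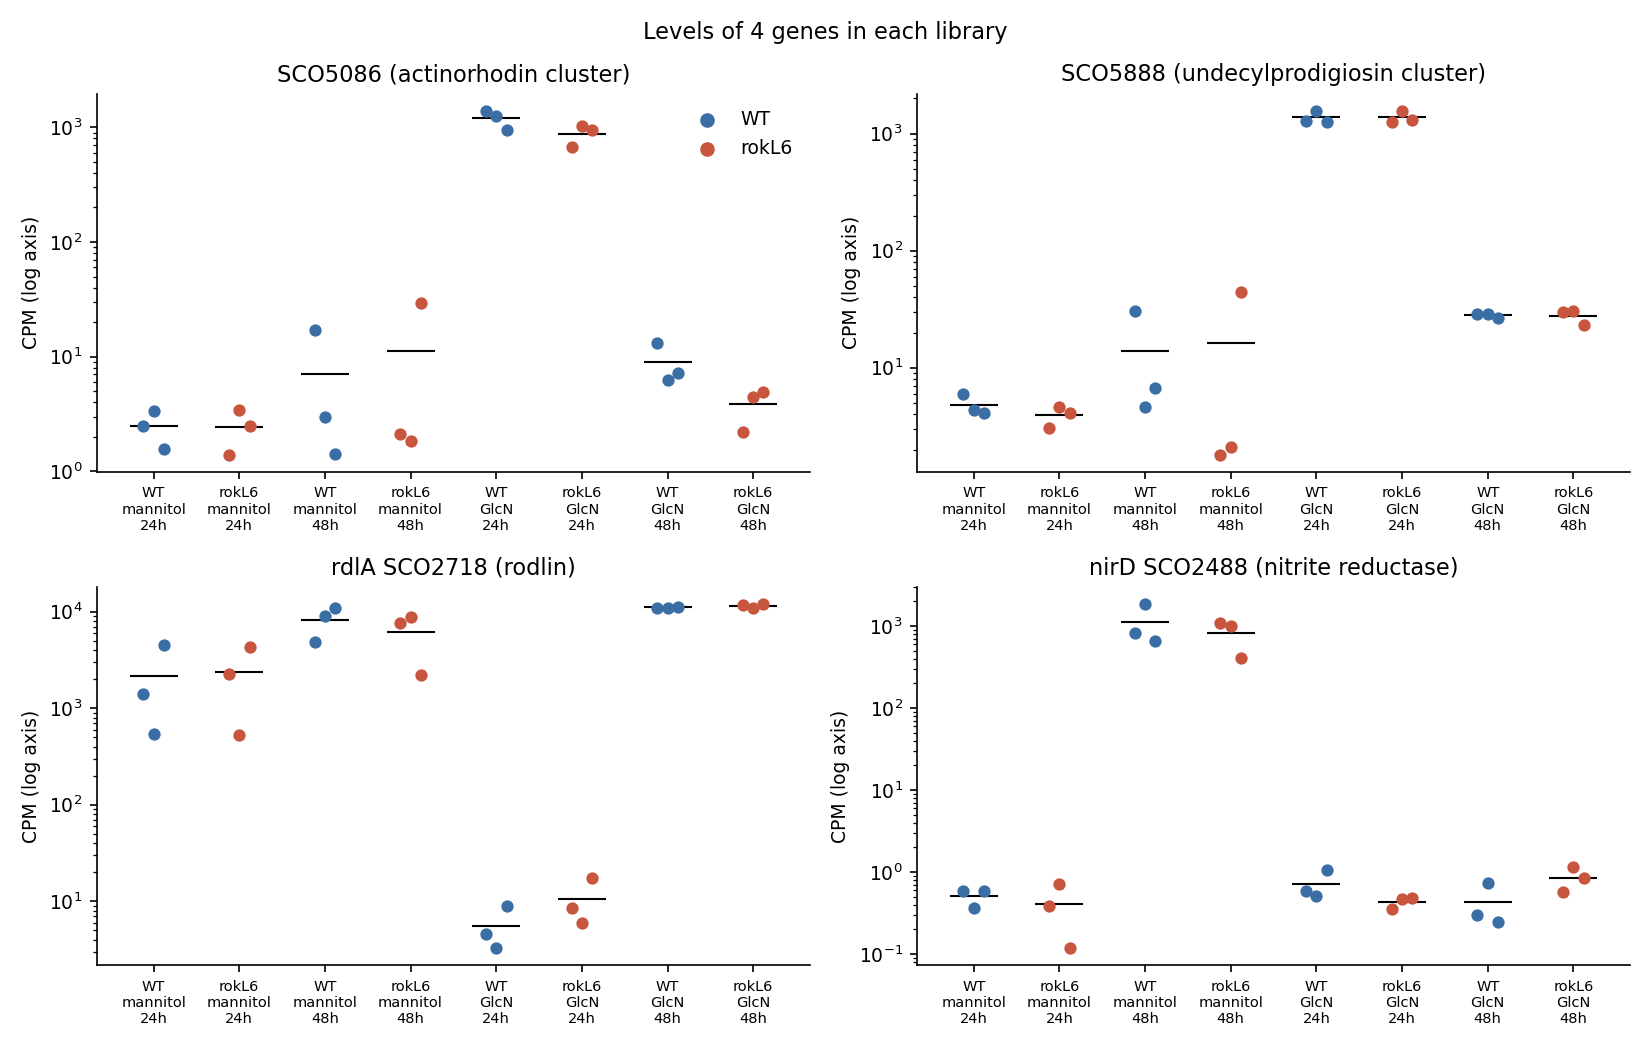
CPM (log axis) of 4 genes in each library by group, WT in blue and rokL6 in red, with the group mean as a line. SCO5086 and SCO5888 are highest in GlcN at 24 h and rdlA lowest there, while nirD is highest in mannitol at 48 h.

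Of the 37 lists, camera found 10 higher and 6 lower with GlcN at 24 h in WT and as many in rokL6. Where it is not given, the count adjusted over the list alone was the same. All 22 genes of the actinorhodin cluster rose in both strains (medians 7.39 in WT and 6.99 in rokL6), as did all 22 of the undecylprodigiosin cluster (medians 6.81 and 6.94). Both lists passed camera (adjusted p 1.71e-38 to 3.25e-33) and passed in both strains with an estimated correlation (0.022 in WT and 0.0164 in rokL6 for either list). In the coelimycin cluster 19 of 20 genes rose in each strain (medians 3.31 and 2.21). The WT call held with an estimated correlation (0.022), and in rokL6 it was lost with adjusted p = 0.0878 with an estimated correlation. Without the atypical libraries neither held (adjusted p 0.233 and 0.383). In the cluster for the calcium-dependent antibiotic (CDA) 36 and 35 of 40 genes rose, and 37 and 36 adjusted over the list alone (medians 3.75 and 3.49). It was lost with adjusted p = 0.714 with an estimated correlation.

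All 10 chaplin and rodlin genes fell with GlcN at 24 h in both strains (medians -5.06 in WT and -4.49 in rokL6). Their camera calls ended with adjusted p = 0.108 with an estimated correlation in WT and 0.118 in rokL6. In the list of whi and other sporulation genes 1 of 13 rose and 5 fell in each strain (medians -0.27 and -0.26), and its camera calls were lost with adjusted p = 0.828 and 0.755 with an estimated correlation. Of its members whiH (SCO5819) fell in WT (-3.37), and ssgA (SCO3926) in WT (-3.12) and in rokL6 (-2.84). All 11 coelichelin genes fell in WT, and 6 of 11 in rokL6 with 7 adjusted over the list alone (medians -1.29 and -0.68). The 4 genes of the ectoine cluster, for an osmoprotectant, rose in both strains (medians 2.94 and 2.63). In the hopanoid lipid cluster 11 of 13 genes rose in each strain, with 12 adjusted over the list alone in rokL6 (medians 1.31 and 1.36). In gas vesicle cluster 1, 10 and 9 of 10 genes rose, with 10 adjusted over the list alone in rokL6 (medians 2.06 and 1.55). The other 4 lists of this paragraph ended in adjusted p = 0.31 to 0.728 with an estimated correlation.

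The list for uptake and breakdown of amino sugars moved in both directions with GlcN at 24 h and did not pass camera in either strain (adjusted p 0.815 in WT and 0.377 in rokL6), while it passed in rokL6 by fry (0.0075). In WT 5 of 19 genes rose and 6 fell, and its median (-0.18) and mean (0.15) differed in sign. In rokL6 6 rose and 4 fell, with 7 and 5 adjusted over the list alone. nagK (SCO4285), for an N-acetylglucosamine kinase, rose from 14.9 ± 1.33 to 53 ± 3.49 CPM in WT (1.83 ± 0.16, adjusted p 2.42e-08) and by 2.06 in rokL6. The sugar transporter gene ngcG (SCO6007) rose by 2.15 and 2.62. dasA (SCO5232), for a chitobiose-binding protein, fell from 85 ± 9.87 to 24 ± 4.52 CPM in WT and also in rokL6 (-1.64). In the pentose phosphate pathway 7 of 12 genes rose in WT, where 1 fell adjusted over the list alone, and 6 rose in rokL6. Its transketolase gene tkt (SCO6663) rose by 3.56 and 3.16. The camera call of the pathway was lost with adjusted p = 0.562 with an estimated correlation in WT and 0.714 in rokL6, and in rokL6 without the atypical libraries (0.0874).

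At 48 h, 698 genes rose and 1031 fell with GlcN in WT, and 1096 rose and 1982 fell in rokL6. The pair of atypical libraries is in the mannitol groups here, and the median over all genes was -0.17 and -0.17. Without the pair, 1383 rose and 1592 fell in WT and 1460 rose and 1541 fell in rokL6, with 1617 and 1942 of the genes shared with the full set. With RLE scaling 810 rose and 757 fell in WT, and 1199 rose and 1409 fell in rokL6. By DESeq2 939 rose and 908 fell in WT, and 1325 rose and 1500 fell in rokL6. Fitted on the 6 libraries of each comparison alone, 889 genes passed in WT and 305 in rokL6. In WT the count was 2606 without mannitol replicate 3, and 1133, 1145 and 1137 without GlcN replicate 1, 2 or 3. In rokL6 it was 1924 without mannitol replicate 3, and 1615, 1648 and 1606 without GlcN replicate 1, 2 or 3. Of the genes past the test in both strains, 1403 of 1404 moved in the same direction (r = 0.934 across genes).

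The nitrite reductase genes were among those that fell with GlcN at 48 h. nirD (SCO2488) fell from 1109 ± 649.5 to 0.429 ± 0.27 CPM in WT (-11.27 ± 0.60, adjusted p 6.15e-11) and also in rokL6 (-9.93). The changes were -10.73 and -10.37 for SCO2487, and -6.11 and -5.20 for nnaR (SCO2958), a regulator gene of nitrate use. The ribosomal protein genes rpmG (SCO3428) and rpmB (SCO3429) fell in WT (-10.93 and -9.69) and in rokL6 (-8.96 and -9.57). Among the rises, the chitosanase gene csnA (SCO0677) went from 26 ± 3.8 to 211 ± 8.23 CPM in WT (3.02 ± 0.16, adjusted p 5.36e-11) and rose by 3.02 in rokL6. SCO5083 and SCO5084 of the actinorhodin cluster rose by 5.71 and 5.52 in WT and by 3.75 and 3.59 in rokL6. In rokL6 these 2 calls were lost with only the 6 libraries fitted (adjusted p 0.0671 and 0.0565). SCO1448 did not pass in WT (-1.15, adjusted p 0.0894) or in rokL6 (0.21, adjusted p 0.72). In WT the change was -0.03 (adjusted p 0.982) without mannitol replicate 1, an atypical library, and it passed without mannitol replicate 3 (−1.50, adjusted p 0.0239).

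In the nitrogen assimilation list 11 of 14 genes fell with GlcN at 48 h in each strain and gdhA (SCO4683), for glutamate dehydrogenase, rose (medians -5.61 in WT and -5.32 in rokL6). Adjusted over the list alone, 13 fell in WT and 12 in rokL6. Its camera call (adjusted p 4.32e-27) held in WT with an estimated correlation (0.0387), and in rokL6 it was lost with adjusted p = 0.109 with an estimated correlation. Without the pair it held in both (0.00326 and 0.00126). In the NADH dehydrogenase list 13 and 14 of 14 genes rose (medians 1.13 and 1.07), and all 7 arginine biosynthesis genes rose in both strains (medians 0.82 and 1.01). In the hopanoid cluster 7 and 13 of 13 rose, with 12 adjusted over the list alone in WT. These 3 lists were lost with adjusted p = 0.314 to 0.917 with an estimated correlation. In the undecylprodigiosin cluster 6 of 22 genes rose in each strain, and 20 in each without the pair, with adjusted p = 0.921 and 0.582 with an estimated correlation. In the CDA cluster 9 and 34 of 40 genes fell, and 29 and 37 adjusted over the list alone, and its calls were lost with adjusted p = 0.967 and 0.707 with an estimated correlation. Without the pair 5 and 3 fell and camera did not pass (adjusted p 0.129 and 0.15), and without WT mannitol replicate 1 or rokL6 mannitol replicate 3 alone it did not pass either (adjusted p 0.183 and 0.215).

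**Figure D4:**
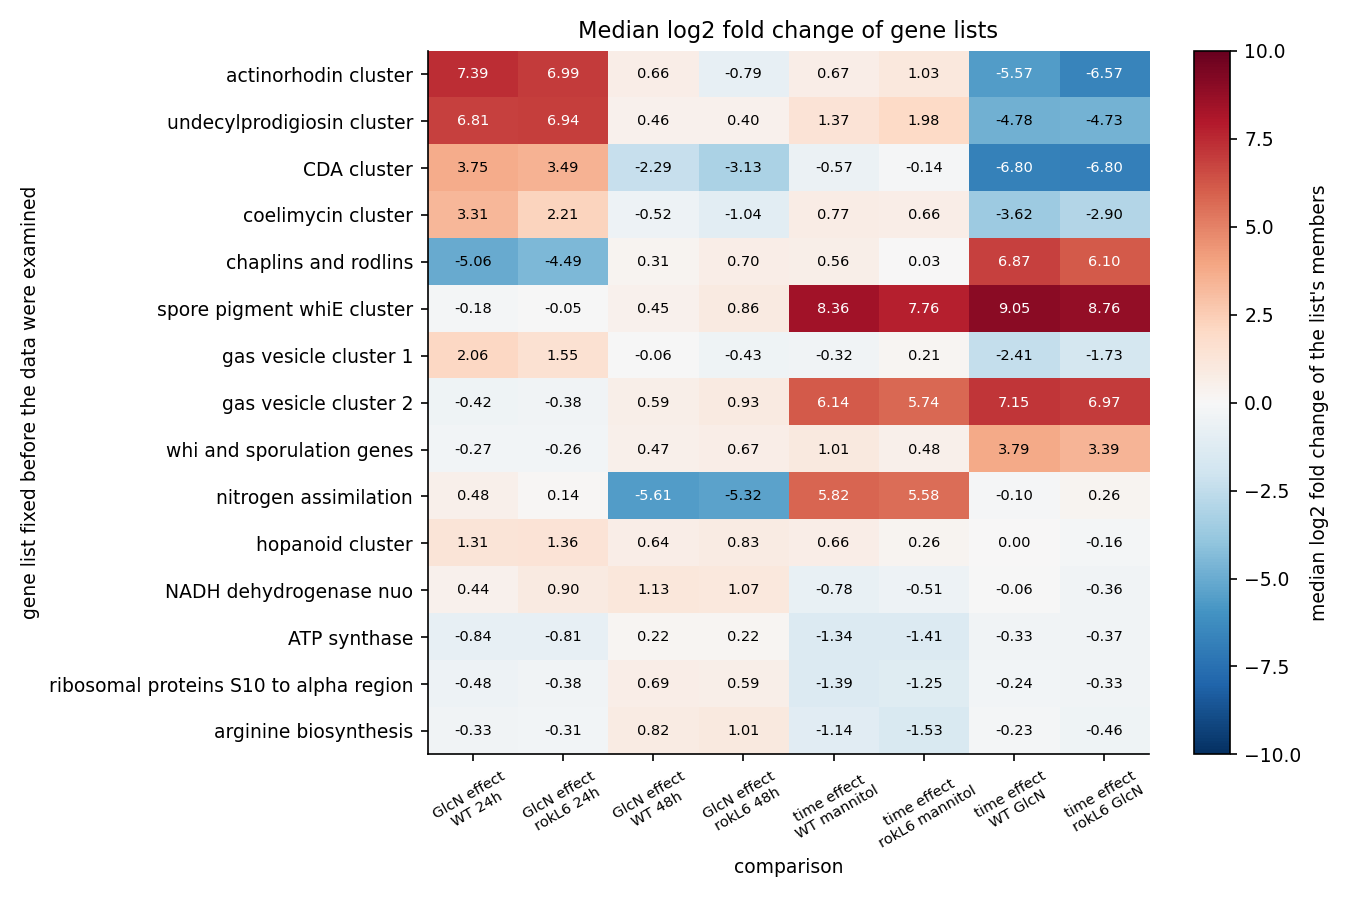
Median log2 fold change of the members of 15 gene lists (vertical) in the 4 GlcN effects and the 4 time effects (horizontal), written in each cell and coloured from blue (lower) to red (higher). The actinorhodin cluster has medians of 7.39 and 6.99 with GlcN at 24 h, and −5.57 and −6.57 from 24 h to 48 h in GlcN.

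The next question was what differed between 24 h and 48 h in each strain and medium. In mannitol, 2371 genes rose and 1537 fell in WT, and 2919 rose and 1660 fell in rokL6. The median over all genes was 0.28 and 0.36, and without the pair of atypical libraries 2456 rose and 2348 fell in WT and 2408 rose and 2259 fell in rokL6. Fitted on the 6 libraries alone, 1859 genes passed in rokL6. nirD rose from 0.515 ± 0.131 to 1109 ± 649.5 CPM in WT (11.03 ± 0.59, adjusted p 8.71e-12) and by 10.96 in rokL6. SCO5317 of the spore pigment cluster rose by 8.63 and 8.32, and SCO6185, in a cell wall glycan cluster, by 7.05 and 7.12. exaC (SCO1174), for an aldehyde dehydrogenase, fell from 3242 ± 299.8 to 44.9 ± 2.73 CPM in WT (-6.17 ± 0.27, adjusted p 7.70e-13) and also in rokL6 (-6.23). The amino sugar transporter gene nagE1 (SCO2906) rose by 4.18 and 4.16, and SCO4740, annotated as glmS, by 2.84 and 2.63.

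Camera found 8 lists higher and 8 lower over time in mannitol in WT, and 6 and 10 in rokL6. In the list of the SigE envelope stress genes and the cell wall glycan cluster, the 12 glycan genes rose and sigE and its 3 partners (SCO3356 to SCO3359) fell in both strains (medians 5.18 and 5.29). It passed with an estimated correlation (0.00752 in WT and 0.0164 in rokL6). All 8 genes of the spore pigment cluster (medians 8.36 and 7.76) and all 10 of gas vesicle cluster 2 (medians 6.14 and 5.74) rose in both strains. In the nitrogen assimilation list 13 of 14 genes rose in WT and 12 in rokL6, and gdhA fell (medians 5.82 and 5.58). These 3 lists were lost with adjusted p = 0.14 to 0.216 with an estimated correlation. Without the atypical libraries the spore pigment list passed that test in WT (adjusted p 0.0343). Of 25 ribosomal protein genes 25 fell in WT and 23 in rokL6, where 25 did adjusted over the list alone (medians -1.39 and -1.25). All 9 ATP synthase genes (medians -1.34 and -1.41) and all 7 arginine biosynthesis genes (medians -1.14 and -1.53) fell in both strains. The falls of these 3 lists ended in adjusted p = 0.213 to 0.836 with an estimated correlation. The chaplin and rodlin list did not pass (adjusted p 0.885 in WT and 0.455 in rokL6). In WT 4 of 10 rose and 2 fell, with a median of 0.56 while camera pointed down. In rokL6 2 rose and 4 fell, with 3 higher adjusted over the list alone, a median of 0.03 and a mean of -0.03.

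In GlcN, 1836 genes rose and 1945 fell from 24 h to 48 h in WT, and 1808 rose and 1849 fell in rokL6. Without the atypical mannitol libraries 5405 and 5330 genes passed, the 3781 and 3657 among them. rdlA rose from 5.56 ± 2.92 to 11087 ± 125 CPM in WT (10.96 ± 1.06, adjusted p 2.15e-08) and by 10.09 in rokL6, and chpD by 10.90 and 9.99. SCO3222 of the CDA cluster fell from 452 ± 31.1 to 0.681 ± 0.178 CPM in WT (-9.33 ± 0.73, adjusted p 1.11e-09) and also in rokL6 (-9.16). The sporulation genes sigF (SCO4035) and ssgB (SCO1541) rose by 7.93 and 6.05 in WT and by 7.40 and 5.73 in rokL6. SCO1448 fell in WT (-3.43 ± 0.50, adjusted p 7.44e-06).

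Camera found 5 lists higher and 5 lower over time in GlcN in each strain, and none of the 10 per strain held with an estimated correlation. All 22 actinorhodin genes (medians -5.57 and -6.57) and all 22 undecylprodigiosin genes (medians -4.78 and -4.73) fell in both strains. In the CDA cluster 37 and 36 of 40 genes fell (medians -6.80 and -6.80). In the coelimycin cluster 18 of 20 fell in each strain, with 19 adjusted over the list alone in WT (medians -3.62 and -2.90). The chaplin and rodlin genes rose, 10 of 10 in WT and 9 in rokL6 (medians 6.87 and 6.10). In the list of whi and other sporulation genes 11 of 13 rose and sapA (SCO0409) fell in both strains (medians 3.79 and 3.39). All 8 spore pigment genes rose (medians 9.05 and 8.76). All 10 genes of gas vesicle cluster 2 rose (medians 7.15 and 6.97) and all 10 of cluster 1 fell (medians -2.41 and -1.73), in both strains. These 9 lists gave adjusted p = 0.118 to 0.797 with an estimated correlation. Without the atypical libraries the undecylprodigiosin list passed that test in rokL6 (adjusted p 0.0384) and not in WT (0.0706). The tenth, of SigE and cell wall glycan genes (12 rose and 4 fell in both strains), gave 0.0672 in WT and 0.0603 in rokL6.

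The last question was whether the effect of GlcN differed between the strains (the effect in rokL6 minus that in WT). At 24 h, 3 genes passed, SCO0638 (-4.67 ± 0.45, adjusted p 1.28e-05), SCO0632 (-4.60 ± 0.75, adjusted p 0.0171) and SCO0637 (-1.78 ± 0.29, adjusted p 0.0171). In mannitol these genes were higher in rokL6, and in GlcN SCO0638 stood at 7.87 ± 1.23 CPM in rokL6 and 8.91 ± 0.591 CPM in WT. The call of SCO0632 ended without WT mannitol replicates 1, 2 or 3, rokL6 mannitol replicate 3, WT GlcN replicates 2 or 3 or rokL6 GlcN replicates 1, 2 or 3 (adjusted p 0.0566 to 0.0926), and of SCO0637 without WT mannitol replicates 1 or 2, rokL6 mannitol replicate 3, WT GlcN replicates 2 or 3 or rokL6 GlcN replicates 1, 2 or 3 (adjusted p 0.0561 to 0.0926). The count was 7 without WT GlcN replicate 1. It was 1 without WT mannitol replicate 1 or 2, rokL6 mannitol replicate 3, WT GlcN replicate 2 or 3, or rokL6 GlcN replicate 1, 2 or 3. Without the atypical libraries it was 13, by DESeq2 12, with RLE scaling 5 and with these 12 libraries fitted alone 8, where SCO0637 did not pass (adjusted p 0.0747). SCO1448 did not pass (-3.52 ± 0.67, adjusted p 0.0558). It passed with the replicate number as a block (0.0377), with these 12 libraries fitted alone (1.95e-06), by DESeq2 (5.88e-05), with RLE scaling (0.0476) and without the atypical libraries (7.02e-10). Of the lists, coelimycin (median -1.08, adjusted p 0.0223), carotenoid (-2.69, 0.0398) and coelichelin (0.83, 0.0427) passed camera with an estimated correlation, with 0 members past the edgeR test. None of these 3 lists passed by fry (adjusted p 0.205, 0.276 and 0.217). Adjusted over the list alone, 9 of 20, 4 of 7 and 3 of 11 passed. Without the atypical libraries the adjusted p with an estimated correlation was 0.22, 0.31 and 0.31.

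At 48 h, 3 genes passed the test of the difference between the GlcN effects, SCO5265 (2.08 ± 0.25, adjusted p 3.25e-04), SCO5264 (1.90 ± 0.23, adjusted p 3.25e-04) and SCO5263 (0.99 ± 0.17, adjusted p 0.0381). In GlcN SCO5265 stood at 40.6 ± 1.01 CPM in rokL6 and 39.1 ± 2.55 CPM in WT. The call of SCO5263 ended without WT mannitol replicates 2 or 3, rokL6 mannitol replicates 1 or 2, WT GlcN replicates 1, 2 or 3 or rokL6 GlcN replicates 1, 2 or 3 (adjusted p 0.0576 to 0.393). The count was 10 without WT mannitol replicate 1, 20 without rokL6 mannitol replicate 3, 5 without rokL6 GlcN replicate 1 and 56 without both atypical libraries. SCO5263 did not pass by DESeq2 (adjusted p 0.0971) or with RLE scaling (0.465). With these 12 libraries fitted alone 0 genes passed by edgeR, against 276 with an unadjusted p under 0.05 in the fit of all libraries and 6 by DESeq2. Camera found 14 lists higher and 5 lower, and 4 higher and 7 lower without the atypical pair, and none of the 19 held with an estimated correlation. For actinorhodin the median was -1.68, with 0 of 22 genes past the edgeR test and 3 lower adjusted over the list alone (adjusted p = 0.16 with an estimated correlation).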

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

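The tests on the counts in silent genes and on a mixture of libraries, on the neighbours of SCO1448 and on the time course of the antibiotic clusters were chosen only after the results were seen, while the splits of the libraries were planned before the data were examined. Their counts by the place of the atypical pair and of the mannitol 24 h pairs in the interaction were taken after the results were seen.

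In the fit of all libraries the effect of GlcN differed between the strains for 6 genes. Of these, SCO0632, SCO0637 and SCO5263 lost their calls without some single libraries. SCO1448 did not pass at 24 h in that fit, but passed by DESeq2 (−3.53, adjusted p 5.88e-05) and in the edgeR fit without the atypical libraries (−3.53, 7.02e-10). SCO1449 passed in these 2 settings too. At 24 h the difference was −4.67 for SCO0638, −4.60 for SCO0632 and −1.78 for SCO0637. At 48 h it was 2.08 for SCO5265, 1.90 for SCO5264 and 0.99 for SCO5263. For lists at 24 h the median difference was −1.08 for the coelimycin cluster, 0.83 for the coelichelin cluster and −2.69 for the carotenoid cluster, with 0 members past the edgeR test. In the carotenoid cluster the WT GlcN 24 h libraries themselves varied, with SCO0185 at 74 ± 85.9 CPM. The same 12 libraries were divided in 100 ways at each time, the real division among them. Strain labels were divided within each medium. Some divisions could therefore keep the strains apart in 1 medium and hold strain effects, so the shares do not measure chance alone. At 24 h 6 of 100 gave as many genes as the real 3, with up to 10 in another, so chance cannot be excluded for that count. Of these, 39 parted the pairs of equal number in mannitol, and 5 of the 39 gave as many, with up to 10 in another. At 48 h 39 of 100 did, with up to 2556 in another, so chance cannot be excluded there either. The 36 divisions with the atypical pair in the same group called 1525 to 2556 genes. Of the 64 with the pair apart, the real one among them, 3 gave at least 3 genes, with up to 11 in another.

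In the strain, GlcN and time comparisons 3 libraries against 3 allow 10 splits, too few for a share under 0.05. The real count and the highest of the other splits were 11 and 40 in mannitol at 24 h (2 splits with as many genes), 14 and 0 in GlcN at 24 h (1 split, the real one), and 25 and 0 in GlcN at 48 h (1). In mannitol at 48 h they were 26 and 4503 (7 splits with as many). The 4 splits with the atypical pair on the same side called 4050 to 4503 genes, and of the 6 with the pair apart 3 had as many as the real one, with up to 62 in another. In mannitol at 24 h the replicate numbers may pair the libraries. There the 3 splits other than the real one that part the 3 pairs called 0 genes at most. The split with 40 genes kept libraries of equal number together. For GlcN the counts were 2611 and 0 (WT, 24 h), 2388 and 0 (rokL6, 24 h), 1729 and 2 (WT, 48 h) and 3078 and 11 (rokL6, 48 h). For time they were 3908 and 0, and 4579 and 1, in mannitol (WT, rokL6), and 3781 and 0, and 3657 and 0, in GlcN. In these 8 comparisons the real split alone gave as many genes (1 of 10).

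The first pattern weighed was the counts in otherwise silent genes in WT mannitol 48 h replicate 1 and rokL6 mannitol 48 h replicate 3. A mixture with or a swap for 1 of the other 22 libraries is argued against. Of 7212 chromosomal genes at any level, 1412 (2449 in the rokL6 library) lay above 2 times the highest of those 22 libraries. For 1 of those 22 set against the rest, the number was 22 at most. The atypical libraries were not set against each other. Wild-type DNA in the rokL6 library is argued against too, with 0 counts of SCO1447 where about 649 were expected. Genomic DNA of each library's own strain may be the source: 96.2% of the 500 silent genes (98.0% in the rokL6 library) lay within 2-fold of the library's median per kb, against 59.0 to 68.4% in the other 22 libraries. By the silent-gene level it would make up about 23.0 and 50.9% of the counts, and no biological explanation was tested.

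The second pattern was the rise of SCO1446, SCO1449 and SCO1450 beside SCO1448 in rokL6. Fragments of the SCO1448 transcript counted in its neighbours may explain part of it, and the rise of SCO1448 with GlcN in WT at 24 h was used as a test. SCO1449 changed there by 2.71 (95% bounds 1.87 to 3.54) against 2.23 predicted from its share in the mutant, so its rise may come from SCO1448 fragments. SCO1446 changed by −0.40 (95% bounds −0.91 to 0.12, predicted 0.30) and SCO1450 by −0.56 (−0.98 to −0.14, predicted 0.22). Both predictions lay above the bounds, so shared fragments alone did not give these values. As the predicted rises were under 1 log2 unit, a change of the genes' own transcripts with GlcN could hide them. For SCO1450, shared fragments in the mutant therefore cannot be told apart from a change of its own transcript. SCO1446 ends at base 1543432, before SCO1448 starts at base 1544766 on the same strand. Fragments of a transcript that starts at SCO1448 would not reach SCO1446. Where that transcript starts in the mutant was not examined. A change caused by the loss of RokL6 stays open for the 3 genes.

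The third pattern was the higher antibiotic clusters and lower chaplins with GlcN at 24 h, with file names that give different hours for both media. A later point on the same course between both mannitol times is argued against for libraries at or between those times. The 3 WT GlcN 24 h libraries lay outside the 6 WT mannitol libraries, on the side of the GlcN effect, for 22 of 22 actinorhodin genes, 22 of 22 undecylprodigiosin genes and 10 of 10 chaplin and rodlin genes. The median change over time in WT mannitol was 0.67, 1.37 and 0.56 for the 3 lists, and -0.15, 0.10 and 0.84 without the atypical pair. A peak or dip between the times sampled may also give such values and stays open, as does an effect of GlcN. A point on the course before that of the mannitol 24 h libraries was not tested.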

How the results depend on the processing

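The fit without both atypical mannitol 48 h libraries was chosen only after the data were seen. The other alternatives were planned.

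Without a low-count filter and without the 10 most abundant genes, the 14 counts of genes past the test stayed within 1.5 times those reported. With RLE size factors the strain count was 9 in GlcN at 24 h and 11 in mannitol at 48 h, and the 24 h interaction had 5. RLE moved the median of all genes from -0.17 to −0.02 (GlcN in WT at 48 h), from -0.17 to 0.00 (GlcN in rokL6 at 48 h), and from 0.28 and 0.36 to 0.13 and 0.18 (time in mannitol, WT and rokL6). DESeq2 gave 17, 24, 84 and 45 genes in the strain comparisons (mannitol 24 h, GlcN 24 h, mannitol 48 h, GlcN 48 h) and 12 and 6 in the interactions. With only the groups compared in the fit, the strain counts were 37, 0 and 95 (GlcN 24 h, mannitol 48 h, GlcN 48 h) and the GlcN counts 4473, 4446, 889 and 305 (WT and rokL6 at 24 h, then at 48 h). The time count in rokL6 mannitol was 1859, and the interactions had 8 and 0. In that fit SCO1447 (−11.55, adjusted p 0.317) and SCO1448 (6.66, adjusted p 0.907) did not pass in mannitol at 48 h. The 2 atypical libraries are then 2 of the 6, and the cause was not tested further.

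Without both atypical libraries the strain counts were 18, 149, 396 and 75, the GlcN counts 4493, 4265 and 2975 (WT 24 h, rokL6 24 h, WT 48 h), and the interactions had 13 and 56. The common coefficient of variation is lower there (0.138 against 0.335). SCO1448 changed direction, not past the test, for GlcN in rokL6 at 48 h (−0.19, and −0.19 to 0.48 without 1 replicate, lowest without rokL6 mannitol 48 h replicate 3) and in the 48 h interaction (−0.16). SCO3428 did so for time in rokL6 GlcN without rokL6 GlcN 48 h replicate 2 (range −0.55 to 1.12). The causes were not tested.

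Leaving out each replicate in turn gave counts of 8 to 15 (strain, mannitol 24 h), 5 to 30 (GlcN 24 h), 11 to 776 (mannitol 48 h, highest without WT replicate 1) and 10 to 31 (GlcN 48 h). For GlcN they were 2092 to 2291 and 1839 to 2060 at 24 h and 1133 to 2606 and 1606 to 4168 at 48 h (WT, rokL6). For time they were 3237 to 4154 and 3733 to 5260 in mannitol and 3371 to 3438 and 3267 to 3336 in GlcN. The interactions gave 1 to 7 and 2 to 20. Of 331 gene results, 286 kept their side of the threshold in each of these fits, and 131 of 2040 values fell short of it.

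With the replicate number as a block, as the shared numbers of the libraries allow, the counts were 9, 10, 28 and 25 (strain), 2528, 2289, 1547 and 2385 (GlcN), 3695, 4194, 3739 and 3593 (time) and 4 and 3 (interactions). Of 331 gene results 320 stayed on their side. In 3 of the 12 comparisons checked, each of the 6 libraries correlated best with its own number. Outside the strain comparison in mannitol at 24 h, SCO7843, SCO0005, SCO6564 and crtI (each adjusted p 0.0740, strains in GlcN at 24 h), SCO3479 (0.0531, mannitol 48 h) and SCO3705 (0.10, GlcN 48 h) did not pass with the block. With it, SCO1448 (24 h interaction, 0.0377), SCO2493 (strains in GlcN at 48 h, 0.0398) and SCO7682 (time in rokL6 GlcN, 0.0416) passed.

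For the fixed gene lists, 37 over 14 comparisons, camera with the preset correlation made 187 calls, and 19 of these held with an estimated correlation. The number was 183 with the block, 171 without the atypical libraries and 172 to 206 without 1 replicate. By fry, which tests direction and not a list against other genes, 146 lists passed. Among 118 list results followed, and besides the losses in the report, camera calls that fry did not pass were the chaplin and rodlin list (0.433, strains in GlcN at 24 h), arginine biosynthesis (0.990, strains in GlcN at 48 h), the CDA cluster (0.133 and 0.0794, GlcN at 48 h), the sporulation list (0.0509, GlcN in WT at 24 h), actinorhodin and phosphate starvation (0.423 and 0.123, 48 h interaction), the SCO1447 neighbours (0.399, 24 h interaction), chitinases (0.0794, GlcN in rokL6 at 48 h) and ribosomal proteins (0.237 and 0.358, GlcN at 24 h). Of the 118, some not given in the report, 3 of 744 values without 1 replicate changed direction and 12 fell short. The chaplin and rodlin list for time in WT mannitol changed direction by fry (adjusted p 0.585), without both atypical libraries (0.875) and without WT mannitol 24 h replicate 3 or 48 h replicate 1 (0.690 and 0.799, range 0.690 to 0.826). The amino sugar list did so for GlcN in WT without both atypical libraries (0.912 at 24 h, 0.953 at 48 h) and without WT mannitol 48 h replicate 1 (0.937 at 48 h, range 0.205 to 0.937). None of these passed, and the cause was not tested.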

Other observations

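The genes and regions of this part were chosen after their values were seen, and no tests beyond those of the 14 comparisons were run on them.

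The csn operon SCO2657 to SCO2662, for uptake of chitosan oligosaccharides, rose with GlcN. At 24 h the 6 genes rose in both strains, by 4.18 to 7.31 in WT and by 4.34 to 8.14 in rokL6. SCO2658 went from 2.54 ± 0.935 to 408 ± 50 CPM in WT (7.31 ± 0.81, adjusted p 6.27e-07) and from 1.93 ± 0.582 to 549 ± 48 CPM in rokL6. At 48 h 6 genes rose in WT (median 2.01) and 4 in rokL6 (median 1.52), and 6 in each without the atypical libraries (medians 2.63 and 2.56). From 24 h to 48 h in GlcN the 6 genes fell in both strains (medians -2.62 and -2.87). Between the strains the medians were -0.05 and 0.41 at 24 h (mannitol and GlcN) and 0.60 and 0.12 at 48 h, and 0.23 in mannitol at 48 h without the atypical libraries.

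The 6 genes SCO3425 to SCO3430 include genes for ribosomal proteins of the kind without zinc-binding motifs. All 6 rose over time in mannitol (medians 9.37 in WT and 8.87 in rokL6) and fell with GlcN at 48 h (medians -9.84 and -8.88). So did 11 of 11 genes of the coelibactin cluster SCO7681 to SCO7691, with medians of 5.87 and 5.71 over time and -5.96 and -6.06 with GlcN. The 3 zinc uptake genes SCO2505 to SCO2507 had medians of 4.91 and 4.64 over time and -5.17 and -4.97 with GlcN, with each gene past the test. SCO2505 went from 148 ± 3.4 to 6205 ± 2231 CPM over time in WT mannitol (5.39 ± 0.41, adjusted p 7.24e-10). The 5 genes SCO0472 to SCO0476 rose over time in mannitol too (medians 5.57 and 7.19). Among them aztA (SCO0476) was lower in rokL6 in mannitol at 24 h and did not pass in GlcN at 24 h (-2.24, adjusted p 0.0614). Without the atypical libraries aztA (adjusted p 9.73e-04 and 0.0121) and SCO0472 (0.0239 and 0.0266) passed in both media.

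At 48 h the strains were also compared in a pair of chromosome regions. The 14 genes SCO3474 to SCO3487, next to an agarase gene, had medians of 1.33 in mannitol and 1.67 in GlcN, with 6 and 12 past the test and 14 and 14 without the atypical libraries. Single libraries moved these counts. In mannitol the 6 calls ended without WT replicate 2 (adjusted p 0.0860 to 0.148). In GlcN only 8 genes of all tested were higher without WT replicate 1. At 24 h in mannitol 0 of the 14 passed by edgeR (median -0.22), among 137 genes of all tested with an unadjusted p under 0.05 and 17 by DESeq2. Over time in GlcN 12 of these 14 genes were lower in WT (median -1.06) and 8 were higher in rokL6 (median 0.73). The difference between these time effects was not tested. The 21 genes SCO0381 to SCO0401 had medians of -0.51 and -0.52, with 0 past the edgeR test in all libraries and 18 and 15 lower without the atypical pair. Of all genes tested 603 and 125 had an unadjusted p under 0.05 in these comparisons, and DESeq2 found 84 and 45. In this region SCO0385 changed by -0.61 (adjusted p 0.0596, and 0.00131 without the pair) in mannitol and by -0.60 (0.0867, and 0.00201) in GlcN.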
